A study of Homo sapiens with 3 samples.

How the data were processed

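Gene expression was measured in HT-29 cells, an established human colonic adenocarcinoma line with epithelial features, after 3 h with 1 of 3 treatments. Poly(I:C), a synthetic double-stranded RNA that stands in for viral RNA, was given at 10 µg/ml, per the labels. PC was a combination of probiotic strains whose members are not given in the sources used here, and the meaning of the dose printed beside it is unclear, so no dose of PC is reported. PC+poly(I:C) was the combination of both. Each treatment was hybridised on 4 2-colour arrays against RNA of unchallenged HT-29 cells, with treated RNA in Cy5 on 2 arrays and in Cy3 on the other 2. The series' design calls the 4 arrays of a treatment biological replicates, and how the cultures were kept apart is not given in the sources used here. The arrays of poly(I:C) and of PC carry the numbers 1, 2, 4 and 5 for treated and control RNA alike, so the same control RNA may stand on both sets; those of PC+poly(I:C) are numbered B3, B5, B6 and B8 and have their own controls.

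RNA was extracted with TRIzol and RNeasy columns, reverse transcribed with SuperScript III and coupled to Cy3 or Cy5, per the labels' protocols. Per the file headers, the deposited spot intensity and local background of each channel came from the scanner's histogram quantification on a linear scale, with no background subtraction and no crosstalk correction. Each array held 3168 spots in 6 blocks, of which 2754 carried 1352 gene names, 186 were empty and 228 had no name. R 2.13.0 and limma are listed in the submitters' processing notes. The authors' deposited value table holds 1 log2 value per gene and treatment, with no probe column and with its order, centring and direction unstated. Its 1352 values, set against the array's names in alphabetical order, correlated across genes with the fitted log2 ratios of treated over control at r = 0.986 for poly(I:C), 0.967 for PC+poly(I:C) and 0.968 for PC; in order of appearance on the array r was -0.0446 for poly(I:C). Genes are not independent replicates, so these correlations describe the match only. The columns' medians were 0.00705, -0.00394 and 0.00452 and their slopes on the fitted ratios were 0.879, 0.779 and 0.822. What set those slopes is not given in the sources used here.

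For the PC+poly(I:C) arrays the sources conflict over which dye held the treated RNA. The image names in the scanner headers give treated RNA in Cy5 on B3 and B5 and in Cy3 on B6 and B8, and the sample descriptions give the opposite. For poly(I:C) and PC both sources give the same orientation. The header orientation was used throughout and is likely, because the authors' deposited column of that treatment runs the same way (r = 0.967 across genes), but it is not settled. Every comparison that uses these arrays is therefore also given with the orientation of the descriptions, called the description direction.

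Background was corrected with normexp and an offset of 50, ratios were normalised within each array by loess over the named spots, spots marked unreliable by the scanner software were left out, and the spots of a probe were averaged. The brightest probe stood for each gene. A gene was tested when it lay above the 95th percentile of the empty spots in either channel on at least 2 arrays of a treatment, which left 1323 of 1352 names and left out 29. Of the names, 1329 stood on 2 spots and 23 on more; 1240 were current gene symbols, 1325 were matched to a gene table and 27 kept the array's name only. The array's own names are used, so IL8 is CXCL8, IL29 is IFNL1, IL28B is IFNL3, G1P2 is ISG15, TRIF is TICAM1 and BF is CFB. Poly(I:C) array 5 had 356 unreliable spots, against 4 to 34 on each other array, so that IL8, TNFAIP3, NFKBIA, BCL3, CDKN1A, OASL, CXCL11, TAP1 and SMAD1 rest on 3 poly(I:C) arrays. The number of arrays limits the precision, as do unreliable spots and the signal over background, for which the count of genes above the empty spots is given per treatment.

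All 12 arrays entered 1 linear model in limma 3.58.1 (R 4.3.3, with statmod 1.5.0) with 3 treatment coefficients, signed by dye, and a gene-specific dye term, which left 8 residual degrees of freedom and a median of 12.5 after moderation by eBayes. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the 1323 genes, and genes at an adjusted p under 0.05 are called. Each treatment was set against control, the treatments were set against each other, and the departure from additivity was PC+poly(I:C) minus poly(I:C) minus PC on the log2 scale. Every p-value of a gene or list is limma's, and log2 ratios carry the standard error (SE) of the fit. Where 1 side of a gene was not well above background on every array of a group, the fold is given as a lower bound, taken from the lowest signal above background on each array.

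Gene lists of 21 groups were tested: type I and III interferons, interferon-stimulated antiviral genes, double-stranded RNA sensing, Toll-like receptor signalling, NOD-like receptors and inflammasome, NF-kappaB components, chemokines, proinflammatory cytokines, anti-inflammatory genes, JAK-STAT signalling, AP-1 and immediate early factors, MAP kinases and their phosphatases, antimicrobial peptides, complement, junctions and mucins, leukocyte adhesion, antigen presentation, apoptosis, heat shock, leukocyte markers and housekeeping genes. The list test was camera with a preset correlation between genes of 0.01, adjusted over the lists of a comparison, with camera at an estimated correlation and fry beside it. Median, mean and test had the same sign for each of the 31 list calls; among the 116 list tests that did not pass they differed in sign in 42, which were 5 for poly(I:C), 5 for PC and 8 for PC+poly(I:C) against control, 7 for PC+poly(I:C) against poly(I:C), 8 for PC+poly(I:C) against PC, 5 for PC against poly(I:C) and 4 for the departure from additivity. Genes are named by rule: in each treatment the 14 largest rises and 10 largest falls among called genes with the same sign on all 4 arrays before the dye term was taken out, in each difference the 6 largest each way, 48 fixed genes of which 43 were tested, and up to 4 called members of each list described. The groups, the comparisons, the model, the lists, the rule for names and the first set of alternative settings were fixed before the data were examined. Of the fixed genes, RSAD2, DDX58, NOD2 and ATF3 were not among the array's names and IL6 was left out by the filter. The values of 1 other fixed gene are not reported here.

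The alternative settings fixed first were other background corrections (none, subtraction), print-tip loess, median centring, scaling between arrays, no filter, the mean over probes, no dye term, a dye term per treatment, the treatments compared fitted alone, array weights, a variance trend with robust moderation, replicate number and scan batch as blocks, thresholds of 0.01 and 0.1 for the overlap, and leaving out each array. Chosen after seeing the data were the description direction, keeping the unreliable spots, leaving out poly(I:C) replicates 1 and 5 together (both of its arrays with treated RNA in Cy3), scan batch as a random block for the differences, and a dye term per treatment, the description direction and leave-one-out for the lists. The arrays fell into 5 scan batches, each with arrays of 1 treatment: all 4 of poly(I:C) in the first, B3 and B5 in the next, B6 and B8 in another, and PC 1, 4 and 5 apart from PC 2. Scan batch and treatment therefore cannot be told apart in any comparison between treatments. Within PC+poly(I:C), scan batch and dye cannot be told apart either. By the headers, B3 and B5 held treated RNA in Cy5, and B6 and B8 held it in Cy3. The 12 arrays lay on 11 slides.

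The model was tested on simulated data, 10 runs of 1323 genes with 200 changed per treatment. At a log2 change of 1 it recovered 98.9% of changed genes for poly(I:C), 97.7% for PC and 98.5% for PC+poly(I:C) against control, and 92.9%, 93.3%, 92.3% and 85.8% for PC+poly(I:C) against poly(I:C), PC+poly(I:C) against PC, PC against poly(I:C) and the departure from additivity. At a log2 change of 0.5 the same shares were 66.8%, 67.7%, 67.5%, 41.9%, 42.9%, 38.0% and 31.1%. False calls were 2.92% to 5.33% of calls, and none of 1470 tests of unchanged lists passed (0 of 1470). Simulated errors were drawn independently for each gene, so the list tests were not tried on lists whose genes vary together. Errors also took the fit's own moderated spread, with a dye effect common to the treatments. With 200 changed genes the adjustment is milder than where few genes change. Recovery may therefore be lower in the real data, above all for PC, where 2 genes were called. JUN (-1.34) and MX1 (1.00), for example, did not pass with PC. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.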

Results

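Expression of 1323 genes was compared in HT-29 cells after 3 h with poly(I:C), with a probiotic combination (PC) or with both, each on 4 arrays against unchallenged cells. Genes above the empty spots numbered 895.5 ± 247 (SD, n = 4) per poly(I:C) array, 1126 ± 162 (SD, n = 4) per PC array and 1024.5 ± 149 (SD, n = 4) per PC+poly(I:C) array. Log2 ratios are treated over control ± SE. For called genes against control they rest on 4 arrays with the same sign on all 4, the dye term taken out, unless a number is given, and adjusted p-values are limma's. The direction of every PC+poly(I:C) value is likely but not settled, because the scanner headers and the sample descriptions name opposite dyes for the treated RNA on those arrays. Values follow the headers, and the description direction is given beside each comparison.

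After poly(I:C), the analogue of viral double-stranded RNA, chemokines that attract neutrophils rose 12.6- to 18.0-fold. CXCL1 rose by a log2 of 4.17 ± 0.26, IL8 by 4.06 ± 0.33 (n = 3, 3 of 3), CXCL3 by 3.89 ± 0.15 and CXCL2 by 3.65 ± 0.15. The epithelial interleukin IL17C rose 16.5-fold (4.04 ± 0.24). The tumour necrosis factor family ligands LTB and TNF rose 12.7- and 11.9-fold (3.66 ± 0.15 and 3.58 ± 0.22). CCL20, which attracts dendritic cells, rose 12.4-fold, CX3CL1 11.3-fold and the interferon-inducible lymphocyte chemokine CXCL10 10.2-fold. Adjusted p-values of these 10 genes lay between 3.2e-09 and 3.6e-06. The myeloid growth factors CSF2 and CSF1 rose 9.28- and 7.22-fold. The type III interferons IL28B and IL29 rose 3.41- and 3.26-fold (1.77 ± 0.20 and 1.71 ± 0.23). IFNB1, a type I interferon, had a log2 ratio of 0.23 ± 0.15 (adjusted p = 0.491), and CCL5 had 0.19 (adjusted p = 0.349).

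Among 22 NF-kappaB components, the transcription factors of inflammation and their inhibitors, 10 rose and 12 did not pass. Adjusted over the list alone, 11 were higher and 1 was lower. TNFAIP3, a ubiquitin-editing brake on the pathway, rose 12.5-fold (3.65 ± 0.25, n = 3, 3 of 3). BCL3, a nuclear member of the inhibitor family, and the inhibitor NFKBIA rose 8.91- and 5.63-fold (n = 3, 3 of 3 for both), NFKBIE rose 5.60-fold and the subunit NFKB2 5.58-fold. The list's median log2 ratio was 0.33, above 0 on 4 of 4 arrays (adjusted p = 1.6e-12, and adjusted p = 0.0054 with an estimated correlation). BIRC3, an inhibitor of apoptosis induced by NF-kappaB, rose 6.64-fold. Of 35 proinflammatory cytokines 11 rose and 24 did not pass, and 11 were higher and 2 lower adjusted over the list alone. Their median was 0.15 (adjusted p = 7.9e-08, and adjusted p = 0.0132 with an estimated correlation), or 0.08 without array 2, and IL32 rose 4.74-fold and IL1B 1.72-fold. Of 41 chemokines 9 rose and 32 did not pass, and 9 were higher adjusted over the list alone. The chemokine median was 0.07 (adjusted p = 8.5e-08, and adjusted p = 0.25 with an estimated correlation), or 0.13 without array 1. CCL2, a monocyte chemokine, had a log2 ratio of -0.02.

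Of 33 interferon-stimulated antiviral genes 6 rose and 27 did not pass, and 6 were higher adjusted over the list alone. The transcription factor IRF1 rose 3.90-fold (1.96 ± 0.13, adjusted p = 2.6e-07). The exonuclease ISG20 rose 2.74-fold, OASL 2.58-fold (n = 3, 3 of 3), GBP1 2.54-fold and IFIT2 2.49-fold. Other classical members had values of 0.18 for IFIT1, 0.45 for G1P2, 0.49 for MX1, 0.44 for OAS1 and 0.36 for IRF7. None of those 5 passed, at adjusted p between 0.178 and 0.798. The list had a median of 0.30, above 0 on 4 of 4 arrays (adjusted p = 0.0052, and adjusted p = 0.591 with an estimated correlation). Without poly(I:C) array 2 its median was 0.21 (adjusted p = 0.0648) and without array 1 0.18 (adjusted p = 0.0252), and OASL was no longer called without array 1 (0.72, adjusted p = 0.0688). Of 12 genes of double-stranded RNA sensing 2 rose and 10 did not pass, and 3 were higher adjusted over the list alone. They were the Toll-like receptor adaptor TRIF (2.40-fold, 1.26 ± 0.15) and the kinase IKBKE (2.30-fold, 1.20 ± 0.10). The sensing list had a median of 0.21 (adjusted p = 0.0328, and adjusted p = 0.25 with an estimated correlation). It did not pass without array 1 or 2 (adjusted p = 0.106 and 0.0719). The receptors themselves had values of -0.05 ± 0.13 for TLR3 (adjusted p = 0.910) and 0.42 for IFIH1 (adjusted p = 0.318, 3 of 4 arrays above 0). CXCL11, an interferon-inducible chemokine, rose 2.48-fold (n = 3, 3 of 3). Of 19 interferons 2 rose and 17 did not pass, and 3 were higher adjusted over the list alone (adjusted p = 0.731).

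Of 13 AP-1 and immediate early factors, transcribed within the first hours of stimulation, 4 rose and 9 did not pass, and 11 were higher adjusted over the list alone. JUN rose 3.63-fold (1.86 ± 0.29), NR4A1 2.57-fold, JUNB 2.37-fold and EGR1 2.11-fold (1.08 ± 0.27, adjusted p = 0.0243). The list's median was 0.48, above 0 on 4 of 4 arrays (adjusted p = 0.0018, and adjusted p = 0.25 with an estimated correlation). EGR1 was not called without array 1, 2 or 5 (adjusted p = 0.0714, 0.0958 and 0.0855). FOS had a value of 0.93 ± 0.27 (adjusted p = 0.0651). Of 34 JAK-STAT genes 8 rose and 26 did not pass, and 8 were higher adjusted over the list alone. They included the receptor chains IFNGR2 (3.00-fold) and IFNAR2 (1.96-fold), STAT5A (2.59-fold) and the cytokine receptor subunit IL6ST (1.88-fold). The feedback inhibitors SOCS1 and SOCS3 rose 1.75- and 1.60-fold. The JAK-STAT median was 0.15 (adjusted p = 0.0240, and adjusted p = 0.25 with an estimated correlation). That call was lost without array 1 (0.03, adjusted p = 0.138) or array 4 (adjusted p = 0.050). Of 41 MAP kinases and phosphatases 6 rose and 35 did not pass, and 6 were higher adjusted over the list alone (adjusted p = 0.825). The phosphatases DUSP1 and DUSP5 rose 3.05- and 2.37-fold.

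Barrier and immune-recognition genes gave few calls. Of 29 junction and mucin genes 2 rose and 27 did not pass, and 2 were higher adjusted over the list alone (adjusted p = 0.825). The tight junction gene CLDN1 rose 1.74-fold and the secreted mucin MUC2 1.61-fold, and TJP1 had a value of -0.10. Complement had 2 of 7 higher, and 2 adjusted over the list alone (adjusted p = 0.151). BF rose 3.51-fold and C3 at least 1.60-fold, its control not well above background. Antigen presentation had 2 of 27 higher, and 2 adjusted over the list alone (adjusted p = 0.825). Its members TAP1 (n = 3, 3 of 3) and HLA-F rose 1.65- and 1.54-fold. TAP1 was not called without array 1 or 2 (adjusted p = 0.282 and 0.129), and HLA-F not without any 1 of the 4 arrays (adjusted p = 0.0601 to 0.184). Leukocyte adhesion had 1 of 15 higher, and 1 adjusted over the list alone (adjusted p = 0.914), which was ICAM1 at 2.83-fold. Toll-like receptor signalling had 1 of 30 higher, the kinase IRAK2 at 2.00-fold, and 1 adjusted over the list alone (adjusted p = 0.507). NOD-like receptors and inflammasome genes had 1 of 12 higher, the kinase RIPK2 at 1.58-fold, and 1 adjusted over the list alone (adjusted p = 0.786). Antimicrobial peptides had 1 of 12 higher, and 1 adjusted over the list alone (adjusted p = 0.914), with DEFB1 at 0.13. Anti-inflammatory genes had 1 of 21 higher, and 2 adjusted over the list alone (adjusted p = 0.947), with IL10 at -0.37 and TGFB1 at 0.33. Apoptosis had 2 higher and 1 lower of 29, and the same counts adjusted over the list alone (adjusted p = 0.947). Of 16 heat shock genes, 27 leukocyte markers and 7 housekeeping genes limma called 0, also adjusted over the list alone (adjusted p = 0.681, 0.507 and 0.419).

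In all, poly(I:C) changed 86 genes, 83 higher and 3 lower, with 51 over 2-fold and 21 over 4-fold. The 3 that fell were the growth factor BMP4 (-0.82 ± 0.16, adjusted p = 0.0048), the death receptor adaptor FADD (-0.56 ± 0.10) and the cell cycle inhibitor CDKN1B (-0.52 ± 0.14, adjusted p = 0.0487). BMP4 was not called without array 1 (-0.68, adjusted p = 0.0520), FADD not with median centring (-0.37, adjusted p = 0.104), and CDKN1B not with median centring (-0.32, adjusted p = 0.394) or without any 1 of the 4 arrays (adjusted p = 0.0641 to 0.233). Without a dye term EGR1, JUNB, RIPK2, TAP1, HLA-F and CDKN1B were not called (adjusted p = 0.0550 to 0.197). Without poly(I:C) arrays 1 and 5, the one with fewest genes above the empty spots and the one with most unreliable spots, 51 genes were called. Those are also the only poly(I:C) arrays with treated RNA in Cy3, so that the 2 left have 1 dye orientation. Of the genes named above, BMP4, FADD, CDKN1B, IL29, IFIT2, OASL, IL1B, IL32, JUN, JUNB, EGR1, NR4A1, DUSP1, SOCS1, SOCS3, IL6ST, IRAK2, MUC2, CLDN1, TAP1 and HLA-F were not called then (adjusted p = 0.050 to 0.684). With the poly(I:C) arrays fitted alone IL1B, EGR1, DUSP1, MUC2, TAP1 and HLA-F were not called (adjusted p = 0.0526 to 0.230). Array weights ended the calls of CDKN1B, TAP1 and HLA-F (adjusted p = 0.0920 to 0.120), and keeping unreliable spots that of HLA-F (adjusted p = 0.0826). With a dye term per treatment 136 genes were called.

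**Figure D1:**
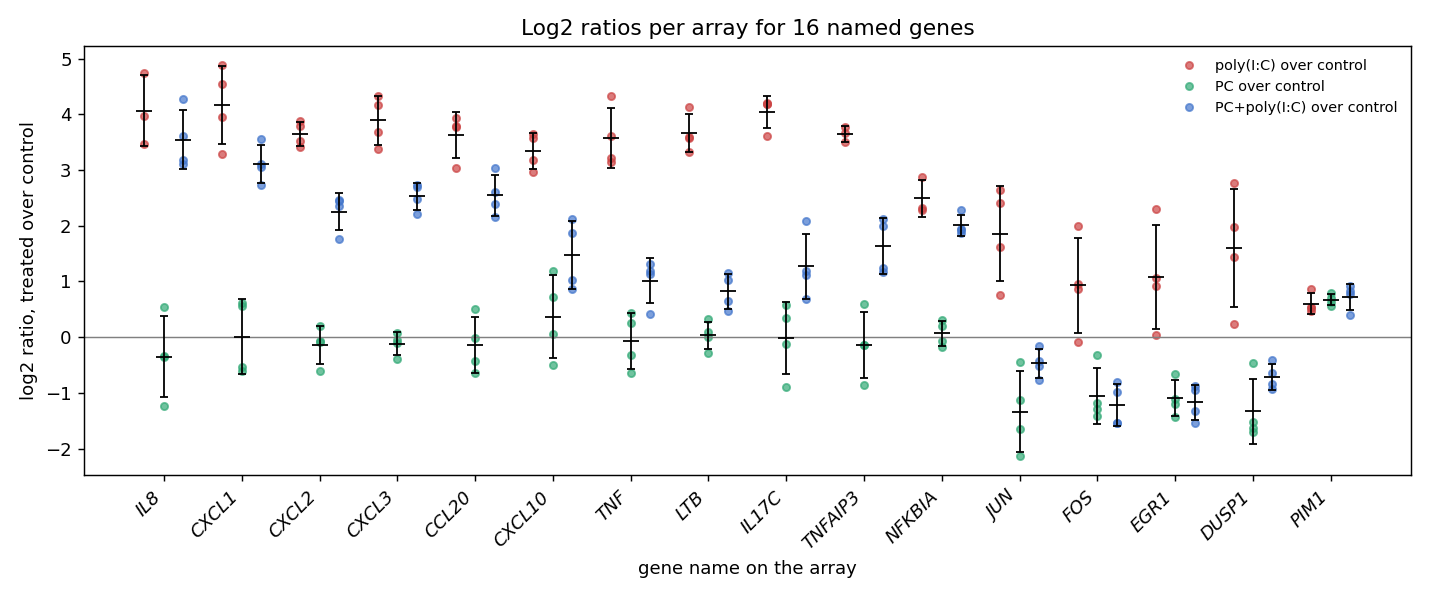
Log2 ratios of treated over control for 16 named genes, with 1 point per array, colours for the 3 treatments and a black bar with whiskers for the mean ± SD. CXCL1 had fitted values of 4.17 with poly(I:C), 0.01 with PC and 3.11 with PC+poly(I:C), and the PC+poly(I:C) points change sign in the description direction.

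With PC alone, 2 genes passed. PIM1, a growth-promoting kinase, rose 1.59-fold (0.67 ± 0.11, adjusted p = 0.0272), and CDKN2B, an inhibitor of the cell cycle, fell by 0.65 ± 0.10 on the log2 scale (adjusted p = 0.0272). The chemokines and cytokines that poly(I:C) raised had values of 0.01 for CXCL1, -0.14 for CCL20, -0.07 for TNF and -0.35 ± 0.28 for IL8 (adjusted p = 0.880). NFKBIA had 0.07 and BIRC3 -0.24. Immediate early genes had values below 0 that did not pass, -1.34 ± 0.29 for JUN, -1.33 ± 0.31 for DUSP1 and -1.10 ± 0.27 for EGR1 (each adjusted p = 0.116, 4 of 4 arrays). FOS had -1.05 ± 0.27 (adjusted p = 0.144, 4 of 4). Interferon-stimulated genes had values above 0 that did not pass. On 4 of 4 arrays these were 1.00 ± 0.25 for MX1 (adjusted p = 0.121), 0.70 ± 0.20 for G1P2 and 0.64 ± 0.16 for OAS1, and on 3 of 4 arrays 0.77 ± 0.25 for IFIT1 and 0.72 ± 0.21 for IFIH1.

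As a group, the 33 interferon-stimulated antiviral genes stood higher than other genes with PC. Limma called 0 of the 33 over all genes, and 19 were higher adjusted over the list alone. The median log2 ratio was 0.38, with quartiles of 0.23 and 0.70 (adjusted p = 1.2e-19, and adjusted p = 0.483 with an estimated correlation). The medians on the 4 arrays were -0.04, 0.31, 1.11 and 0.59, and without array 1 the list's median was 0.65. The 13 AP-1 and immediate early factors stood lower, with 0 called over all genes and 3 lower adjusted over the list alone. Their median was -0.15 (adjusted p = 0.00042, and adjusted p = 0.483 with an estimated correlation), with -0.16, 0.01, -0.23 and -0.46 on the 4 arrays. Without PC array 5 it was -0.06 (adjusted p = 0.0682). Antigen presentation stood higher, with 0 of 27 called and 1 higher adjusted over the list alone. Its median was 0.15 (adjusted p = 0.00042, and adjusted p = 0.483 with an estimated correlation), and it did not pass without PC array 4 or 5 (adjusted p = 0.110 and 0.0682). NF-kappaB components had a median of -0.04 (adjusted p = 0.194), chemokines 0.06 and cytokines -0.05 (adjusted p = 0.887 for both).

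Over all genes 107 had an unadjusted p under 0.05 in limma, against 66.15 expected by chance, and 2 passed the adjustment. PIM1 and CDKN2B were not called without PC array 2, 4 or 5 (adjusted p of PIM1 0.140, 0.154 and 0.180, of CDKN2B 0.105, 0.154 and 0.172). Both calls were also lost with median centring, print-tip loess or no dye term, with the PC arrays alone, and with unreliable spots kept. The count was 13 with array weights and 11 without PC array 1.

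After PC and poly(I:C) together, 7 of 41 chemokines rose against control, while the list did not pass with an estimated correlation (adjusted p = 0.256). IL8 rose 11.7-fold (3.55 ± 0.28, adjusted p = 8.1e-06), CXCL1 8.63-fold (3.11 ± 0.26), CCL20 5.85-fold (2.55 ± 0.20), CXCL3 5.77-fold (2.53 ± 0.15), CXCL2 4.77-fold (2.25 ± 0.15) and CX3CL1 4.11-fold. Of the NF-kappaB components, NFKBIA, BCL3 and TNFAIP3 rose 4.02-fold (2.01 ± 0.13, adjusted p = 2.3e-06), 3.53-fold and 3.11-fold. BIRC3 rose 3.16-fold, CXCL10 2.77-fold, CSF2 2.44-fold, CSF1 2.42-fold, IL17C 2.41-fold and TNF 2.02-fold (1.02 ± 0.22, adjusted p = 0.0242). The immediate early genes FOS and EGR1 fell, with log2 ratios of -1.22 ± 0.27 and -1.17 ± 0.27. DUSP6, a phosphatase of the ERK pathway, fell (-0.88 ± 0.15), and so did SPRY1, an inhibitor of receptor signalling (-0.51 ± 0.12). The beta-catenin gene CTNNB1 (-1.07 ± 0.21), CDKN2B (-0.72 ± 0.10) and the coactivator gene CREBBP (-0.71 ± 0.10) fell too. RAC3 (-0.65 ± 0.14), ACVR2A (-0.58 ± 0.10) and APOL3 (-0.45 ± 0.11, adjusted p = 0.0491) completed the 11 lower genes. In the description direction each of these signs turns, so that risen reads as fallen.

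Of 41 chemokines 7 rose and 34 did not pass, and 7 were higher adjusted over the list alone. Their median was 0.10 (adjusted p = 7.2e-10, and adjusted p = 0.256 with an estimated correlation), or 0.07 without B5 and 0.18 without B6. Of 22 NF-kappaB components 8 rose and 14 did not pass, and 9 were higher and 3 lower adjusted over the list alone. That median was also 0.10, above 0 on 4 of 4 arrays (adjusted p = 8.2e-07, and adjusted p = 0.105 with an estimated correlation), or 0.16 without B6 and 0.04 without B8. Cytokines had 6 of 35 higher, and 7 higher and 1 lower adjusted over the list alone (adjusted p = 0.277). AP-1 and immediate early factors had 2 higher and 2 lower of 13, and 3 higher and 3 lower adjusted over the list alone (adjusted p = 0.782). NR4A1 rose 1.64-fold and the TGF-beta response factor KLF10 1.45-fold. Of the 33 interferon-stimulated genes 1 rose, IRF1 by 1.83-fold (0.88 ± 0.13), and 32 did not pass. The same count held adjusted over the list alone, and the median was -0.10 (adjusted p = 0.686). IFIT1 had -0.37, IFIT2 0.08 and MX1 -0.14. Double-stranded RNA sensing had 2 of 12 higher, and 2 adjusted over the list alone (adjusted p = 0.782), TRIF by 1.70-fold and IKBKE by 1.35-fold. JAK-STAT genes had 2 of 34 higher, and 4 adjusted over the list alone (adjusted p = 0.903), IFNGR2 by 1.74-fold and IFNAR2 by 1.37-fold. ICAM1 rose 2.16-fold and TAP1 1.62-fold. The interferon IL29 had a value of 0.09 (adjusted p = 0.938), SOCS1 of -0.23 and JUN of -0.47 ± 0.29 (adjusted p = 0.573).

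The comparison called 45 genes, 34 higher and 11 lower, 22 of them over 2-fold (11 higher and 34 lower in the description direction). Median centring gave 23 higher and 15 lower of 38. Without array B3 the count was 21, without B5 23, and without a dye term 28. FOS was not called without B3, B5 or B6 (adjusted p = 0.166, 0.215 and 0.0719) and EGR1 not without any 1 of the 4 arrays (adjusted p = 0.0686 to 0.226). Both calls were also lost without a dye term (adjusted p = 0.324 and 0.157) and with scan batch as a random block (adjusted p = 0.0839 and 0.0987). That block also ended the calls of TNF, IKBKE, IFNAR2, NR4A1, KLF10, SPRY1, APOL3 and TAP1 (adjusted p = 0.0575 to 0.128). Without a dye term CSF1, CSF2, IL17C, IKBKE, IFNGR2, IFNAR2, NR4A1, KLF10, SPRY1, APOL3 and TAP1 were lost as well (adjusted p = 0.0550 to 0.245). CXCL10, CSF1, DUSP6 and TRIF were not called without B3 (adjusted p = 0.0643, 0.171, 0.0573 and 0.117) or B5 (adjusted p = 0.0751, 0.248, 0.0603 and 0.125). Without B3, IL17C (0.96, adjusted p = 0.0863) and ACVR2A (-0.52, adjusted p = 0.0573) were not called. CTNNB1 and RAC3 were lost without B3, B6 or B8 (adjusted p = 0.0779 to 0.0939 and 0.0865 to 0.187), and TNF and IFNAR2 without B3, B5 or B6 (0.113 to 0.200 and 0.0894 to 0.221). SPRY1, KLF10 and NR4A1 were lost without B3, B5 or B8 (adjusted p = 0.144 to 0.221, 0.128 to 0.280 and 0.0764 to 0.281), and IKBKE without B5, B6 or B8 (0.112 to 0.229). TAP1 and APOL3 were not called without any 1 of the 4 arrays (adjusted p = 0.0712 to 0.158 and 0.106 to 0.280). Median centring ended the calls of TRIF, IKBKE, IFNAR2, NR4A1, KLF10, TAP1 and APOL3 (adjusted p = 0.167 to 0.436). With the background subtracted or left in, CSF1, TNF, SPRY1, NR4A1 and APOL3 were lost (adjusted p = 0.0671 to 0.270), and with unreliable spots kept TNF, ACVR2A, NR4A1, KLF10 and APOL3 (adjusted p = 0.0527 to 0.326). The PC+poly(I:C) arrays fitted alone lost IKBKE, KLF10 and APOL3 (adjusted p = 0.0629 to 0.0717), and print-tip loess NR4A1 and APOL3 (adjusted p = 0.0641 and 0.0826). APOL3 was also lost with no filter, a dye term per treatment or a variance trend (adjusted p = 0.0504 to 0.0576).

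Set against poly(I:C) alone, 8 of 35 cytokines were lower in cells given PC with poly(I:C) (list adjusted p = 0.0266 with an estimated correlation). LTB lay 7.15-fold lower (-2.84 ± 0.21, adjusted p = 1.3e-05), IL17C 6.84-fold (-2.77 ± 0.34), TNF 5.90-fold (-2.56 ± 0.31) and CSF2 3.81-fold (-1.93 ± 0.30). The immediate early genes JUN, EGR1 and FOS were 5.04-fold (-2.33 ± 0.41, adjusted p = 0.0073), 4.74-fold (-2.25 ± 0.38) and 4.43-fold (-2.15 ± 0.38, adjusted p = 0.0075) lower. The phosphatase DUSP1 was 4.99-fold lower (-2.32 ± 0.44). Of the interferon system, CXCL10 was 3.66-fold, IL28B 3.51-fold, IL29 3.06-fold, GBP1 2.48-fold and ISG20 2.17-fold lower, and IRF1 had -1.09 ± 0.18 (adjusted p = 0.0051). Of the neutrophil chemokines, CXCL2 (-1.40 ± 0.21) and CXCL3 (-1.36 ± 0.22) were called lower, while CXCL1 had -1.06 ± 0.37 (adjusted p = 0.172) and IL8 -0.52 ± 0.43 (adjusted p = 0.607). NFKBIA (-0.48 ± 0.20, adjusted p = 0.277) and ICAM1 (-0.39 ± 0.20, adjusted p = 0.386) did not pass either. The 3 genes that lay higher were the lymphoid factor IRF4 (at least 1.19-fold, not well above background with poly(I:C)), ADCY3 (1.58-fold) and FADD (1.51-fold).

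Of 35 cytokines 8 were lower and 27 did not pass, and 10 were lower adjusted over the list alone. The cytokine median was -0.20 (adjusted p = 6.9e-06, and adjusted p = 0.0266 with an estimated correlation), or -0.11 without poly(I:C) array 2. Of 22 NF-kappaB components 6 were lower, and 10 adjusted over the list alone, with TNFAIP3 4.03-fold and NFKB2 2.64-fold lower. The NF-kappaB median was -0.42 (adjusted p = 6.9e-06, and adjusted p = 0.0205 with an estimated correlation), or -0.27 without that array. The 13 AP-1 factors had 4 lower, and 6 adjusted over the list alone. Their median was -0.59 (adjusted p = 6.9e-06, and adjusted p = 0.287 with an estimated correlation). The 33 interferon-stimulated genes had 5 lower, and 7 adjusted over the list alone. Their median was -0.42 (adjusted p = 1.3e-05, and adjusted p = 0.495 with an estimated correlation). JAK-STAT genes had 4 of 34 lower, and 7 adjusted over the list alone, with SOCS1 2.04-fold, STAT5A 1.88-fold and IFNGR2 1.73-fold lower. The JAK-STAT median was -0.21 (adjusted p = 0.0164, and adjusted p = 0.308 with an estimated correlation), and -0.08 without poly(I:C) array 1 (adjusted p = 0.144). Chemokines had 5 of 41 lower, and 6 adjusted over the list alone (adjusted p = 0.263). CLDN1 was 2.23-fold and the epithelial transcription factor ELF3 2.10-fold lower.

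In all 58 genes differed, 3 higher and 55 lower with PC, 37 over 2-fold. Each called gene named by the rule lay beyond the poly(I:C) mean on 4 of 4 PC+poly(I:C) arrays. Calling genes on these same arrays makes that likely, so it is no separate support. In the description direction 81 differed, 7 higher and 74 lower, and 36 of them were shared. LTB then had -4.49, IL17C -5.31, TNF -4.59, IL8 -7.61 and CXCL1 -7.28, while JUN (-1.39), DUSP1 (-0.89), CLDN1 (-0.43) and SOCS1 (-0.58) were not called (adjusted p = 0.0753 to 0.358). EGR1 (0.10), FOS (0.29), IRF4 (-0.11) and ADCY3 (-0.03) turned sign and were not called (adjusted p = 0.793 to 0.962). List medians in that direction were -0.22 for cytokines (adjusted p = 6.8e-06), -0.28 for NF-kappaB (adjusted p = 4.6e-13) and -0.21 for chemokines (adjusted p = 4.1e-11). With an estimated correlation these were adjusted p = 0.0185 and 0.0111, and the chemokine call was lost (adjusted p = 0.157). The interferon-stimulated genes had -0.13 there (adjusted p = 0.265), and AP-1 -0.38 and JAK-STAT -0.08 (adjusted p = 0.169 for both). Without poly(I:C) arrays 1 and 5 the count was 7, and of the genes named here LTB, IL17C and TNF were still called. Without array 1 it was 37, without B6 34 and without B8 35. It was 30 with no dye term, which lost FOS (adjusted p = 0.129) and GBP1, NFKB2, STAT5A, IFNGR2, ELF3, IRF4, ADCY3 and FADD (adjusted p = 0.0502 to 0.484), 100 with a dye term per treatment and 92 with median centring. Of the 3 higher genes, IRF4 was not called without any 1 of the 8 arrays (adjusted p = 0.0569 to 0.109). FADD was lost without any 1 but poly(I:C) 4 (adjusted p = 0.0552 to 0.0860) and with median centring (0.22, adjusted p = 0.419), which also ended the call of ADCY3 (0.24, adjusted p = 0.342). With only the treatments compared in the fit IRF4, NFKB2 and ELF3 were lost (adjusted p = 0.0902 to 0.0961), and IRF4 with the background left in or subtracted (adjusted p = 0.0576 and 0.0716). ADCY3 and NFKB2 were lost without poly(I:C) 1 or 5, B5, B6 or B8 (adjusted p = 0.0619 to 0.10 and 0.0502 to 0.104), and ELF3 without poly(I:C) 1 or 5, B6 or B8 (0.0723 to 0.111).

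**Figure D2:**
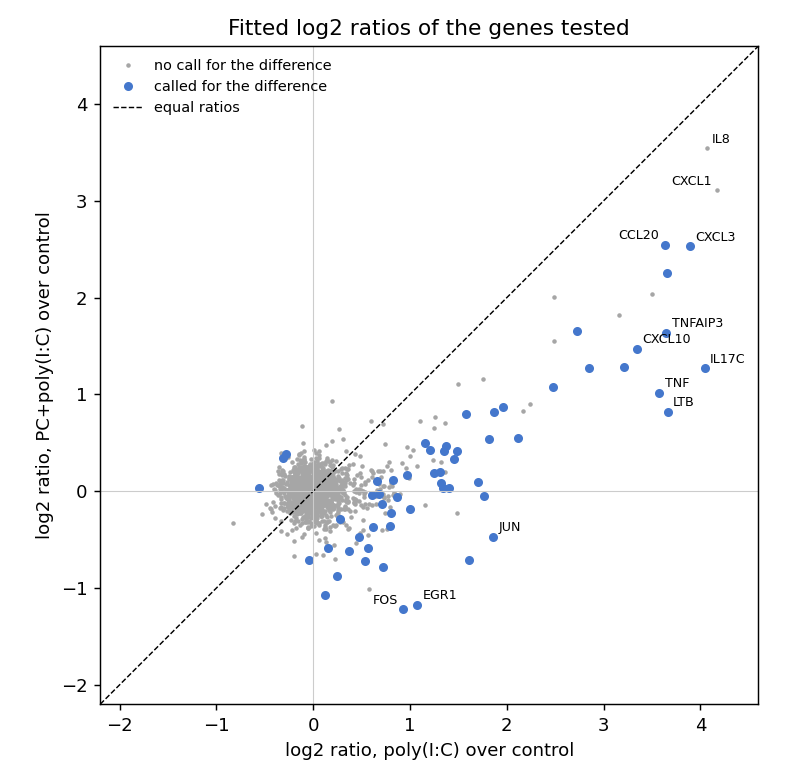
Fitted log2 ratios over control with PC+poly(I:C) (vertical axis) against poly(I:C) (horizontal axis) for 1323 genes, with the 58 genes called for the difference in blue and a dashed line of equal ratios. TNF lies at 3.58 with poly(I:C) and 1.02 with PC+poly(I:C), while IL8 lies at 4.06 and 3.55, and in the description direction the vertical values change sign.

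Set against PC alone, adding poly(I:C) raised IL8 14.9-fold (3.90 ± 0.40, adjusted p = 0.00014), CXCL1 8.59-fold (3.10 ± 0.37) and CCL20 6.46-fold (2.69 ± 0.28). CXCL3 was 6.25-fold (2.64 ± 0.22) and CXCL2 5.26-fold (2.39 ± 0.21) higher. NFKBIA was 3.84-fold, BIRC3 3.72-fold, TNFAIP3 3.42-fold and NFKBIE 2.85-fold higher, followed by CSF2 (2.66-fold), ICAM1 (2.27-fold) and IRF1 (2.00-fold). The interferon-stimulated genes MX1 (-1.15 ± 0.35, adjusted p = 0.249) and IFIT1 (-1.14 ± 0.35, adjusted p = 0.256) did not pass. Nor did TNF (1.09 ± 0.31, adjusted p = 0.249) and CXCL10 (1.11 ± 0.37, adjusted p = 0.315). Chemokines had 6 of 41 higher, and 6 adjusted over the list alone. Their median was 0.10 (adjusted p = 5.4e-09, and adjusted p = 0.214 with an estimated correlation). It was 0.195 without PC array 1, 0.04 without PC 2, 0.05 without PC 4 and 0.06 without B5. NF-kappaB components had 4 of 22 higher, and 8 adjusted over the list alone, with a median of 0.16 (adjusted p = 8.3e-10, and adjusted p = 0.0095 with an estimated correlation). The 33 interferon-stimulated genes went the other way as a group, with 1 higher, and 1 higher and 10 lower adjusted over the list alone. Their median was -0.62 (adjusted p = 7.2e-12, and adjusted p = 0.242 with an estimated correlation), or -0.37 without PC array 4. In all 14 genes were called, each higher. Those named by the rule lay beyond the PC mean on 4 of 4 PC+poly(I:C) arrays.

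The description direction gave 49 genes for PC+poly(I:C) against PC, 20 higher and 29 lower, with 0 shared in direction. IL8 had -3.20 there, CXCL1 -3.12 and CCL20 -2.40, and CSF2 was not called (-1.16, adjusted p = 0.0563). List medians were -0.149 for chemokines, -0.0653 for NF-kappaB and -0.40 for interferon-stimulated genes (adjusted p = 0.638, 0.638 and 0.685 with an estimated correlation). The count of 14 became 7 without PC array 2 or with median centring, 8 without B3 or B5, and 24 with a dye term per treatment. ICAM1 was not called without PC array 2 (adjusted p = 0.0542), TNFAIP3 not without PC 2, B3 or B5 (0.0655 to 0.0746), and IRF1 not without PC 2 or 5, B3 or B5 (0.0551 to 0.0746). NFKBIE was lost without PC 1, 2 or 4, B3 or B5 (adjusted p = 0.0627 to 0.136), and CSF2 without any 1 array but B8 (0.0712 to 0.222). Without a dye term ICAM1 and CSF2 were not called (adjusted p = 0.0604 and 0.402), nor was CSF2 with scan batch as a random block (adjusted p = 0.0568), print-tip loess (0.129) or unreliable spots kept (0.0573). Median centring ended the calls of IRF1, TNFAIP3, ICAM1, NFKBIE and CSF2 (adjusted p = 0.0696 to 0.151). With the background left in ICAM1, NFKBIE and CSF2 were lost (adjusted p = 0.0611, 0.0522 and 0.230), and with it subtracted ICAM1 and CSF2 (adjusted p = 0.0502 and 0.249).

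PC alone and poly(I:C) alone differed in 78 genes, 1 higher and 77 lower with PC. Each called gene named by the rule lay beyond the poly(I:C) mean on 4 of 4 PC arrays. IL8 was 21.3-fold lower with PC (-4.41 ± 0.43, adjusted p = 4.2e-05), CXCL1 17.9-fold (-4.16 ± 0.37) and IL17C 16.8-fold (-4.07 ± 0.34). CXCL3 was 16.1-fold, CXCL2 13.9-fold and TNF 12.5-fold lower. JUN was 9.17-fold (-3.20 ± 0.41), DUSP1 7.67-fold, EGR1 4.51-fold and FOS 3.95-fold lower (-1.98 ± 0.38, adjusted p = 0.0055). FADD was 1.65-fold higher (0.72 ± 0.14), a call that median centring ended (0.51, adjusted p = 0.164), and FOS was not called without a dye term (adjusted p = 0.161). NF-kappaB components had 10 of 22 lower, and 12 adjusted over the list alone, with a median of -0.49 (adjusted p = 2.2e-13, and adjusted p = 0.0028 with an estimated correlation). Cytokines had 10 of 35 lower, and 11 adjusted over the list alone, with a median of -0.20 (adjusted p = 1.0e-06, and adjusted p = 0.0133 with an estimated correlation). AP-1 factors had 5 of 13 lower, and 9 adjusted over the list alone, with a median of -0.71 (adjusted p = 7.5e-06, and adjusted p = 0.155 with an estimated correlation). Chemokines had 8 of 41 lower, and 9 adjusted over the list alone, with a median of -0.09 (adjusted p = 3.5e-06, and adjusted p = 0.414 with an estimated correlation). That median was -0.15 and -0.06 without poly(I:C) array 1 and 2, and -0.18, -0.02, -0.04 and -0.17 without PC array 1, 2, 4 and 5. Of the interferon-stimulated genes 4 were lower and 29 did not pass, with 4 lower adjusted over the list alone and a median of 0.23 (adjusted p = 0.683). MX1 had 0.51 ± 0.35 (adjusted p = 0.553) and IFIT1 0.60 ± 0.35 (adjusted p = 0.471). The count was 47 without poly(I:C) arrays 1 and 5, where FADD and FOS were not called (adjusted p = 0.0859 and 0.0832).

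The departure from additivity asked whether the joint treatment differed from the sum of the separate log2 ratios. Below that sum lay 18 genes, and 0 lay above it. LTB lay 7.30-fold below (-2.87 ± 0.26, adjusted p = 0.00012), IL17C 6.73-fold (-2.75 ± 0.41) and TNF 5.62-fold (-2.49 ± 0.38). CXCL10 lay 4.71-fold (-2.24 ± 0.45), GBP1 4.02-fold, the complement factor BF 3.91-fold, IL28B 3.73-fold and IL29 3.63-fold below. IL8 had -0.17 ± 0.51 (adjusted p = 0.940) and MX1 -1.64 ± 0.43 (adjusted p = 0.118). Of 33 interferon-stimulated genes 2 lay below, and 21 adjusted over the list alone, with a median of -0.96 (adjusted p = 1.6e-20, and adjusted p = 0.178 with an estimated correlation). The poly(I:C) and PC arrays may share control RNA. A shared control low in these genes would enter both subtracted ratios, while the fit takes the arrays as separate. Of 35 cytokines 6 lay below, and 9 adjusted over the list alone, with a median of -0.25 (adjusted p = 2.3e-05, and adjusted p = 0.0400 with an estimated correlation). Of 22 NF-kappaB components 1 lay below, and 9 adjusted over the list alone, with a median of -0.32 (adjusted p = 0.00090, and adjusted p = 0.0400 with an estimated correlation). JAK-STAT genes had a median of -0.15 (3 of 34 below, 5 adjusted over the list alone, adjusted p = 0.0116) and AP-1 factors -0.58 (0 of 13, 0 adjusted over the list alone, adjusted p = 0.0194). Double-stranded RNA sensing had -0.27 (0 of 12, 2 adjusted over the list alone) and complement -0.25 (1 of 7, 1 adjusted over the list alone), each at adjusted p = 0.0217. These 4 calls were lost with an estimated correlation (adjusted p = 0.317, 0.408, 0.337 and 0.337), without poly(I:C) array 1 (-0.07, -0.38, -0.20 and -0.16, adjusted p = 0.0902 each) and in the description direction (adjusted p = 0.178, 0.699, 0.107 and 0.457). The AP-1 call was also lost without PC array 2 (adjusted p = 0.0957), that of sensing without poly(I:C) 2, PC 4 or PC 5 (adjusted p = 0.0602, 0.118 and 0.0859), and that of complement without poly(I:C) 2, PC 4 or B5 (adjusted p = 0.0802, 0.0928 and 0.0772). Medians moved further to -0.27 for JAK-STAT without poly(I:C) 2, -0.39 for AP-1 without B5, -0.17 for sensing without B8 and -0.37 for complement without PC 5.

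For the departure from additivity, limma gave 140 genes at an unadjusted p under 0.05. The description direction gave 87 calls, 14 above and 73 below, and 17 of them were shared. LTB had -4.52 there, and the list medians were -0.71 for interferon-stimulated genes, -0.11 for cytokines and -0.23 for NF-kappaB (adjusted p = 0.536, 0.0438 and 0.0421 with an estimated correlation). The count of 18 became 6 without poly(I:C) array 1 or 2, B6 or B8, and 31 without poly(I:C) array 4. It was 5 with no dye term, which lost IL17C, CXCL10, GBP1 and IL29 (adjusted p = 0.0676 to 0.0937), 55 with a dye term per treatment, 9 with unreliable spots kept, which lost TNF, CXCL10 and IL29 (adjusted p = 0.158, 0.0542 and 0.0592), and 1, LTB, without poly(I:C) arrays 1 and 5. CXCL10 was not called without poly(I:C) 1, 2 or 5, PC 4 or 5, B6 or B8 (adjusted p = 0.0578 to 0.0983). IL28B was lost without poly(I:C) 1 or 2, PC 4, B6 or B8 (0.0536 to 0.0686), and IL29 without any 1 array but poly(I:C) 4 and PC 1 (0.0750 to 0.115).

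**Figure D3:**
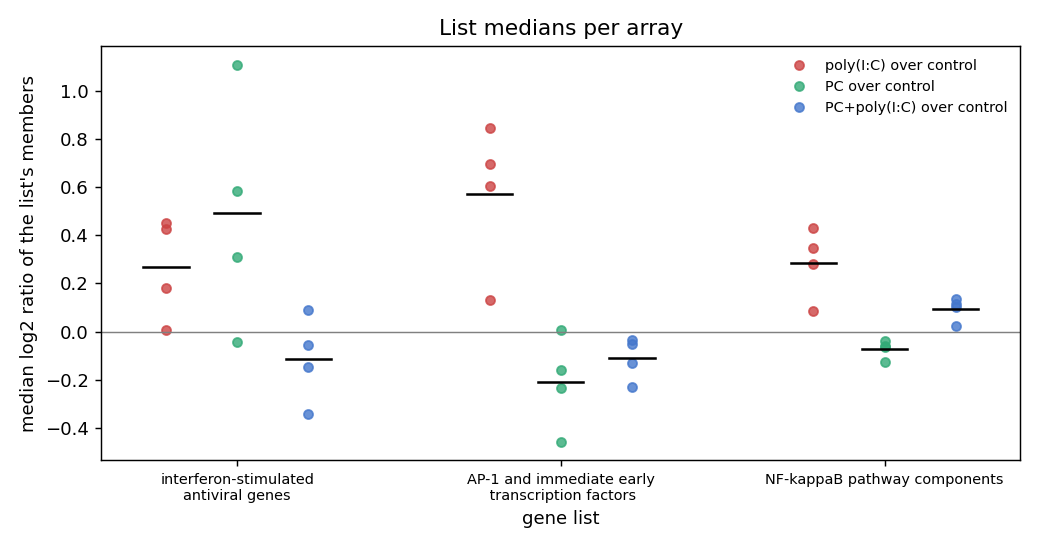
Median log2 ratio over control of the members of 3 gene lists, with 1 point per array, colours for the 3 treatments and a black bar for the mean of the 4 arrays. The interferon-stimulated genes ran from -0.04 to 1.11 with PC, from 0.01 to 0.45 with poly(I:C) and from -0.34 to 0.09 with PC+poly(I:C), whose points change sign in the description direction.

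Genes raised by poly(I:C) were followed across the treatments. Of the 83, 31 also rose with PC+poly(I:C), against 2.1 expected for independent lists (Fisher's exact test over genes, p = 6.3e-37, as a description). In 82 of them the value was lower with PC+poly(I:C) than with poly(I:C), and 46 were called lower. Their median log2 ratio was 1.32 with poly(I:C), 0.37 with PC+poly(I:C) and -0.01 with PC. In the description direction 2 genes were shared. PIM1 was called higher in all 3 treatments, and CDKN2B lower in PC and PC+poly(I:C). Log2 ratios of poly(I:C) and PC correlated across genes at r = -0.056, where unchanged groups against shared controls gave 0.487 (0.416 to 0.558 in 100 simulations). The covariance was -0.0059 against 0.0122, and 1 gene was called in both against 0.01. The simulations held no treatment effect, while the observed ratios hold the changes with poly(I:C). The 2 sets of values therefore cannot decide whether controls were shared. Poly(I:C) and PC+poly(I:C) correlated across genes at r = 0.599 and PC and PC+poly(I:C) at 0.212, and at -0.599 and -0.212 in the description direction. Genes are not independent replicates.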

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

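The tests of the 3 patterns weighed here (lower responses with PC, interferon-stimulated genes with PC alone, and the dye orientation) were chosen after the results were seen; the comparisons of other splits of the arrays were set before.

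The departure from additivity was marked because 18 genes responded to poly(I:C) differently with and without PC in a test of the difference itself, and the 83 genes raised by poly(I:C) had a median log2 ratio of 1.32 without PC and 0.37 with it. A uniform compression of ratios on the PC+poly(I:C) arrays was argued against by the scatter of the genes about a common line of slope 0.463, which was 624 against 97.8 in simulations (simulated share 0.0001, the smallest that 10000 simulations can give). Picking of genes by chance was argued against by poly(I:C) arrays not used for picking, whose median stayed at least 0.699 above the PC+poly(I:C) arrays. Cultures, controls or scans made apart for PC+poly(I:C) may still account for the difference, since 0 scan batches held both treatments. An effect of PC on the response also stays open, as a hypothesis.

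With PC alone, the interferon-stimulated genes had a median log2 ratio of 0.38, while the list did not pass with an estimated correlation (adjusted p = 0.483). Any 1 array as the whole source was argued against, since the median without 1 PC array lay between 0.260 (without array 4) and 0.654 (without array 1). A dye effect that is the same on these arrays cancels in the mean of both orientations by design. That mean had the fit's own median of 0.384 (quartiles 0.23 and 0.70), so it is no separate test of a dye effect. The orientations differed, with medians of 0.92 with treated RNA in Cy5 and 0.12 with Cy3. Control RNA low in these genes and shared with the poly(I:C) arrays may contribute and stays open, with a lowest correlation of same-numbered arrays over the list of -0.127, too close to 0 for 33 genes to decide. An effect of PC itself remains among the open explanations.

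The dye orientation of the PC+poly(I:C) arrays given by the descriptions was set against the authors' deposited column of that treatment. Turned that way, the fitted ratios correlated across genes with the column at -0.967 and with those of poly(I:C) at -0.599, and 2 genes raised by poly(I:C) were shared in place of 31, all of which argue against the descriptions. The direction is not called settled, since the sources conflict, and where the authors took their orientation from is not given in the sources used here.

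Other splits of the arrays were compared with the real one. For each treatment against control, 8 splits are too few for a share under 0.05 (the real split was 1 of 8 in each); the real counts were 86 for poly(I:C), 2 for PC and 45 for PC+poly(I:C) and the highest others 6, 1 and 0. For PC+poly(I:C) against poly(I:C), 1 of 35 splits gave as many as 58 genes (highest other 1). For PC against poly(I:C), 1 of 35 gave as many as 78 (highest other 1). Both argue against a random grouping of the arrays, but scan batch followed treatment, so treatment and batch cannot be told apart. For the departure from additivity, 1 of 100 drawn gave as many as 18 (highest other 5). Those draws shuffled the labels of every treatment, which asks whether the treatments are equal, so they cannot decide additivity. For PC+poly(I:C) against PC, 2 of 35 splits gave as many as 14, so by that share alone chance was not excluded. The other split called 38 and parted the arrays by dye (B3, B5, PC 2 and PC 4 with treated RNA in Cy5, the rest in Cy3). Its dye term rests on the poly(I:C) arrays alone. The 38 calls therefore reflect how the dye effect on the split arrays differs from that on the poly(I:C) arrays. A dye term per treatment gave 24 genes for the real split.

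Single arrays that stood apart from the other 3 of their treatment were marked for 12 of 273 sets of 4 log2 ratios tested, where chance marks about 1 in 20, here 13.65. On poly(I:C) array 1, IL17C had 3.61 (others 4.18 to 4.21), CCL20 3.03 (3.78 to 3.93), IKBKE 1.02 (1.26 to 1.27) and CSF1 3.87 (2.48 to 2.56). On poly(I:C) array 4, IL29 had 0.668 (2.02 to 2.07), IFIT1 -0.352 (0.30 to 0.39) and IRF4 -0.726 (-0.13 to -0.12). On PC array 2, TRIF had 0.0157 (0.32 to 0.34) and DUSP1 -0.465 (-1.71 to -1.53). Among the PC+poly(I:C) arrays, CXCL2 had 1.76 on B5 (2.35 to 2.47), SOCS1 -0.0166 on B3 (-0.32 to -0.28) and SPRY1 -0.183 on B6 (-0.63 to -0.60), with signs turned in the description direction.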

How the results depend on the processing

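The description direction, keeping unreliable spots, leaving out poly(I:C) arrays 1 and 5 and scan batch as a block for differences were chosen after the data were seen, as were the dye term per treatment, description direction and leave-one-out for lists. On 227 called results of named genes, 4903 alternative values kept direction and call in 4300, lost the call in 603 and reversed none (0), leaving aside the description direction and scaling between arrays, which moved no ratio; without poly(I:C) arrays 1 and 5, 101 of 227 were lost, and without a dye term 63 of 227.

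Counts moved as follows; the cause was not tested, and leaving out poly(I:C) arrays 1 and 5 took away both of its arrays with treated RNA in Cy3 as well as lowering their number. Poly(I:C), 86: 136 with a dye term per treatment, 51 without arrays 1 and 5, 75 to 103 leaving out 1 array. PC, 2: 0 with print-tip loess, 0 with median centring, 0 without a dye term, 0 fitted alone, 0 with unreliable spots kept (limma; 107 at an unadjusted p under 0.05 in the model used), 13 with array weights, 4 without poly(I:C) arrays 1 and 5, 0 to 11 leaving out 1 array. PC+poly(I:C), 45: 28 without a dye term, 45 with every sign turned in the description direction, 21 (without B3) to 35. PC+poly(I:C) against poly(I:C), 58: 92 with median centring, 30 without a dye term, 100 with a dye term per treatment, 7 without arrays 1 and 5, 34 (without B6) to 60. PC+poly(I:C) against PC, 14: 7 with median centring, 24 with a dye term per treatment, 49 and mostly lower in the description direction, 7 (without PC 2) to 14. PC against poly(I:C), 78: 47 without arrays 1 and 5, 62 to 83. Departure from additivity, 18: 5 without a dye term, 55 with a dye term per treatment, 87 in the description direction, 9 with unreliable spots kept, 1 without arrays 1 and 5, 6 (without poly(I:C) 1 or 2, B6 or B8) to 31 (without poly(I:C) 4). The overlap of 31 was 20 at 0.01, 34 at 0.1 and 2 in the description direction. The 31 list calls were 9 with an estimated correlation, 36 with fry, 45 with median centring, 33 with print-tip loess, 29 with a dye term per treatment, 28 in the description direction and 24 (without poly(I:C) 1) to 33. In that direction medians turned for NF-kappaB components to -0.0975 (adjusted p = 8.2e-07) and chemokines to -0.104 (adjusted p = 7.2e-10) against control, and to -0.0653 (adjusted p = 0.0213) and -0.149 (adjusted p = 1.3e-05) against PC. With an estimated correlation these calls were lost (adjusted p = 0.105 and 0.256 against control, 0.638 and 0.638 against PC).

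Replicate number as a random block (correlation -0.048) gave 86, 2, 45, 58, 14, 78 and 21 genes in the order above, and as a fixed block over the 8 poly(I:C) and PC arrays 57 in place of 78, without the dye term, which could not be estimated there. Same-numbered arrays deviated with r of -0.10, -0.18, -0.37 and -0.09, and no array correlated best with its own number (0 of 4). Same-numbered arrays share a dye orientation. The common dye term pushes r of such arrays below 0 and r of arrays in opposite orientation above 0. These r therefore cannot decide whether the numbers are pairs, and the model kept no replicate block, as fixed before. With a dye term per treatment r was 0.18, -0.13, -0.13 and 0.19, and shared control RNA was not decided. In that fit the residuals of numbers 1 and 5 mirror each other, as do those of 2 and 4, so these r are not 4 separate checks. Scan batch as a random block (correlation 0.237) gave 126, 2, 34, 61, 13, 90 and 24, of which 86, 2, 34, 57, 13, 78 and 18 were shared. Slide as a block was not run, since its correlation could not be estimated; the departure from additivity cannot be had from fewer treatments, and the value table gives no count. Residuals of arrays of 1 treatment in opposite dye orientation correlated at a median of 0.444 and in the same orientation at -0.147. The fit itself pushes the first value above 0 and the second below 0, so their signs alone show no structure of the samples. Their sizes were not set against those expected from the fit. Dye effects that differ between treatments or scan batches stay open. The split by dye that called 38 genes goes with them. So do the higher counts with a dye term per treatment for poly(I:C), PC+poly(I:C) against either treatment and the departure from additivity. Genes above the empty spots ranged from 555 on poly(I:C) array 1 to 1261 on PC array 1, so fewer genes could be measured well on the arrays with few genes above them.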

Other observations

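Genes of growth control outside the lists were picked after their values were seen. CDKN2B, the cell cycle inhibitor p15, rose 1.45-fold with poly(I:C) (log2 0.53 ± 0.10, n = 4, adjusted p = 0.0032). It fell with PC (-0.65 ± 0.10, adjusted p = 0.0272) and with PC+poly(I:C) (-0.72 ± 0.10, adjusted p = 0.00093), and lay 2.38-fold lower with PC+poly(I:C) than with poly(I:C) (-1.25 ± 0.14, adjusted p = 0.00066). PIM1, a kinase that promotes growth, had log2 ratios of 0.60 ± 0.11 with poly(I:C), 0.67 ± 0.11 with PC and 0.73 ± 0.11 with PC+poly(I:C), each called and on 4 of 4 arrays. The PC calls of both genes were lost without PC array 2, 4 or 5 (adjusted p of CDKN2B 0.105, 0.154 and 0.172, of PIM1 0.140, 0.154 and 0.180). With poly(I:C), CDKN2B was not called with those arrays fitted alone (adjusted p = 0.0787) or without arrays 1 and 5 (adjusted p = 0.113). CDKN1A, the cell cycle inhibitor p21, rose 4.48-fold with poly(I:C) (2.16 ± 0.27, n = 3, adjusted p = 0.00015). It had 0.17 with PC and 0.83 with PC+poly(I:C) (adjusted p = 0.0935). In the description direction the PC+poly(I:C) ratios change sign, and CDKN2B differed from poly(I:C) by 0.18 (adjusted p = 0.583).

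Single genes of bone morphogenetic protein signalling were also picked after their values were seen, and the family was not tested as a group. With poly(I:C), BMP2 rose 4.34-fold (2.12 ± 0.26, adjusted p = 8.6e-05), its signal transducer SMAD1 1.53-fold (n = 3) and the inhibitory SMAD6 1.65-fold, while BMP4 fell (-0.82 ± 0.16, adjusted p = 0.0048). Without poly(I:C) array 1, SMAD1 (0.51, adjusted p = 0.105) and BMP4 (-0.68, adjusted p = 0.0520) were not called, nor were SMAD1, SMAD6 and BMP4 without arrays 1 and 5 (adjusted p = 0.111, 0.421 and 0.521) or SMAD1 with the poly(I:C) arrays fitted alone (adjusted p = 0.0823). With PC+poly(I:C), BMP2 had 0.55 (adjusted p = 0.388) and lay 2.96-fold below poly(I:C) (-1.57 ± 0.37, adjusted p = 0.0291, and -2.67 in the description direction). That difference was lost without poly(I:C) array 1 or 5, B6 or B8 (adjusted p = 0.0812, 0.0981, 0.111 and 0.107), without poly(I:C) arrays 1 and 5 (adjusted p = 0.401) and with only the treatments compared in the fit (adjusted p = 0.10). HBEGF, a ligand of the epidermal growth factor receptor, was 2.84-fold lower with PC+poly(I:C) than with poly(I:C) (-1.51 ± 0.28, adjusted p = 0.0102, and 0.142 without poly(I:C) arrays 1 and 5), and DUSP6, a phosphatase of ERK, 2.18-fold lower (-1.13 ± 0.22, adjusted p = 0.0105). The list of MAP kinases and phosphatases had 4 of 41 lower there and did not pass (adjusted p = 0.429). In the description direction HBEGF had 0.06 (adjusted p = 0.962) and DUSP6 0.62 (adjusted p = 0.146), neither called.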
